A study of Bradyrhizobium sp. ORS 285 with 9 samples.

How the data were processed

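RNA of the ΔbclA mutant of Bradyrhizobium sp. ORS 285 was sequenced in 9 libraries, 3 from each of 3 groups. The groups were cultures in YM, a rich medium, taken at an optical density (600 nm) of 0.5, and nodules of Aeschynomene afraspera and of Aeschynomene indica taken 14 days after inoculation. Plants had each received 2 mL of bacteria at an optical density of 0.1 and grew at 28 °C. Per the labels, libraries were strand-oriented and were read on a SOLiD 5500XL instrument as 50 bp reads. The protocol lists removal of ribosomal RNA and of eukaryotic mRNA for nodule RNA and a hot phenol extraction for culture RNA, so that each comparison with culture also spans these steps. The label of A. afraspera replicate 1 leaves out a word on cell shape that replicates 2 and 3 carry, and it was kept in its group.

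The values are raw counts of reads per gene model, as deposited by the authors, with 1 column of unique reads and 1 of total reads. The deposited tables hold 6983 gene models on 1 sequence, of which 1382 carry a gene symbol, and every model's length is a multiple of 3, so lengths are coding lengths (median 828 bp). The aligner and the name of the genome build are not given in the sources used here, and positions are those of the deposited tables. The tables hold no product text, so gene functions mentioned beside a symbol are general knowledge of genes with that symbol. The deposited tables pair no gene model with the name bclA, and its level is not reported here.

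Counts of unique reads were analysed with edgeR 4.0.16 in R 4.3.3. Gene models with too few reads were removed with filterByExpr (minimum count 10), which left 6657 models, 1373 of them with a symbol. Library sizes were scaled by TMM, and 1 robust quasi-likelihood model with a term for group was fitted to all 9 libraries, with 6 residual degrees of freedom. Tests were two-sided, and a gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Each change is given as log2 fold change ± standard error, the latter being the change divided by the square root of the quasi-likelihood F, and levels are TMM-scaled normalised read counts (CPM), mean ± SD over 3 libraries. Only 3 libraries per group were at hand and the labels do not say whether they came from separate cultures or plants, so p-values measure the spread between these libraries alone. The 3 comparisons were each nodule type minus culture and A. indica minus A. afraspera nodules. TMM scaling takes most genes as unchanged and so centres the changes, whose medians over all genes were 0.0379, 0.0442 and 0.0413. The numbers of higher and lower genes, and small changes, are thus relative to the other transcripts. RLE scaling rests on the same premise. Against culture this premise is in doubt, since 60.2% of genes were called in A. afraspera and 56.1% in A. indica nodules.

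From knowledge of rhizobia, 41 gene lists were fixed before the data were examined, together with the tests, the comparisons and the rule for naming genes. Of these lists 34 had at least 3 tested members and were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01) against all other genes, with Benjamini-Hochberg adjustment over the 34 lists. Each list call was repeated with a correlation estimated from the data and with fry, which asks whether the members move on balance in 1 direction without comparing them with other genes. The remaining 7 lists had fewer than 3 tested members, among them 5 with none.

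Genes are named by a rule. For each comparison it takes the 8 highest and the 8 lowest changes among called genes with a symbol, at least 10 CPM in the higher group and no overlap between the 3 libraries of each group. It adds up to 4 members with the smallest p of each called list, and a fixed set of genes whatever their test. Where a symbol of the fixed set has several copies, the copy with the highest mean CPM was taken. It selected 72, 70 and 63 genes in the 3 comparisons, of which part is printed, and at most 2 gene models without a symbol are given in each direction. Of the fixed set, fixN and fliC had no gene model under that symbol. Any other gene is said to have been chosen after its values were seen. Where a group had 0 counts, a fold is given against a floor of 3 counts over the group, which is not a strict lower bound. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Floors and intervals cover counting error only.

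Depth ranged from 1825446 to 19663337 unique reads per library, and 3 counts correspond to between 0.162 and 1.59 CPM. The method was tested on simulated data, with 200 changed genes placed on unchanged groups. It recovered 60%, 64% and 55% of 2-fold changes and 100%, 95% and 91% of 4-fold changes in the 3 comparisons, and unchanged genes made up 3.61%, 5.92% and 2.67% of the calls. Many more than 200 genes were called in the data (4006, 3732 and 2033 in the 3 comparisons). These rates do not measure errors at that share of change. Equal replicate numbers did not pair the libraries. After group means were removed, correlations across genes between libraries of the same number ran from -0.320 to 0.131, and 1 of 9 libraries was closest to a library of its own number.

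The alternatives fixed in advance were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit on only the 6 libraries compared, a fold threshold, a block for replicate number, the other list tests, CPM on raw totals, and leaving out each library in turn. After the data were seen, counts of total reads and thinning to the smallest library were added. Leaving out ribosomal and transfer RNA features was planned and not run, because the tables name no such feature. No library of a strain with an intact bclA was analysed here, so no comparison measures the effect of the deletion.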

Results

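The transcriptome of a Bradyrhizobium strain lacking bclA, which encodes a peptide transporter related to BacA, was measured by RNA sequencing in free-living culture and in nodules of A. afraspera and A. indica, legumes of the genus Aeschynomene. Each of the 3 groups had 3 libraries. Unique reads on gene models numbered 3284136, 3612703 and 5088760 in culture replicates 1 to 3, 2374747, 19663337 and 5367520 in A. afraspera nodule replicates 1 to 3, and 5437014, 3087445 and 1825446 in A. indica nodule replicates 1 to 3. The 10 most abundant gene models held between 8.66% and 11.02% of the reads of a library.

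Libraries grouped by condition. Spearman correlations across genes, which are not independent replicates, ran from 0.961 to 0.992 within groups and from 0.896 to 0.920 between the nodule types. Between culture and nodules they ran from 0.689 to 0.739 for A. afraspera and from 0.729 to 0.764 for A. indica. The first principal component held 73.4% of the variance and the second 14.4%. Culture replicate 1 stood apart from the other culture libraries in a limited set of genes: of 5338 genes with at least 10 CPM, 183 were more than 2-fold lower in it than in the mean of the others. These included genes of the high-affinity cbb3 oxidase and of denitrification, and the values of the cbb3, denitrification, Calvin cycle and hydrogenase lists against culture are also given without this library. So are the medians of the nitrogenase list.

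The first comparison asks how the mutant's transcripts in A. afraspera nodules differ from those of the free-living culture. Most genes listed for nitrogenase, phosphate uptake and hydrogen uptake rose in A. afraspera nodules, and most listed for photosynthesis, flagella, chemotaxis and ribosomes fell. These list calls were all lost with an estimated correlation (adjusted p 0.0557, 0.0557, 0.652, 0.175, 0.559, 0.652 and 0.931, in that order). Most of the genes tested differed between these groups. Of 6657 genes, 4006 (60.2%) were called, 2075 higher and 1931 lower in nodules, and 2576 of them changed at least 2-fold (1427 higher, 1149 lower). The lower genes were more numerous with no filter on low counts (1998 higher, 2033 lower), without culture replicate 2 (1757 and 1811) and without A. indica replicate 2 (1973 and 2021). This split depends on the scaling, which centres the changes. The 3 libraries of each group did not overlap for 4546 genes (68.3%), where chance gives 10%.

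Nitrogenase genes had some of the highest changes. Transcripts of nifH_1 (positions 1720882 to 1721769), for the nitrogenase reductase, stood at 2190 ± 515 CPM in A. afraspera nodules and 0.756 ± 0.638 CPM in culture (SD, n = 3), a log2 change of 11.56 ± 0.47 (adjusted p 4.05e-09; 12.40 without culture replicate 2). Its near-copy nifH_2 (1749336 to 1750223) rose by 10.69 ± 0.35 (11.64 without culture replicate 3 and 10.04 on total reads), and 29.6% and 29.5% of the reads of these 2 models were not unique and left out. The nitrogenase subunit genes nifD (1721846 to 1723348) and nifK rose by 8.55 ± 0.33 and 8.09 ± 0.34, and nifD reached 4451 ± 815 CPM against 11.9 ± 1.22 CPM. The cofactor gene nifB rose by 8.82 ± 0.38 and the regulator gene nifA by 5.01 ± 0.22. The ferredoxin gene fdxN_2 had 0 counts in culture and, against a floor of 3 counts, was 434-fold higher in A. afraspera nodules. The gene fdxN_1 rose by 8.57 ± 0.41 (9.36 without culture replicate 1, 7.83 without culture replicate 3 and 7.79 on thinned libraries). All 13 members of the nitrogenase list rose, also when adjusted over the list alone, with a median of 7.27 (camera adjusted p 1.08e-26; 0.0557 with an estimated correlation). Without culture replicate 1 this median was 8.10. The fixA, fixB and fixC genes, for electron transfer to nitrogenase, rose by 8.17 ± 0.30, 8.00 ± 0.30 and 8.07 ± 0.27, and these 3 list members had an adjusted p of 1.40e-09 (0.0710 with an estimated correlation).

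All 9 genes of the phosphate and phosphonate list, which holds regulator genes such as phoB beside uptake genes, rose (9 also adjusted over the list alone). Their median was 4.20 (camera adjusted p 2.55e-14; 0.0557 with an estimated correlation). The phosphate-binding protein gene pstS (1490023 to 1491033) stood at 7732 ± 1116 CPM in A. afraspera nodules and 239 ± 15.7 CPM in culture, a change of 5.02 ± 0.20. The regulator gene phoB rose by 5.36 ± 0.29 and the phosphonate transporter gene phnC by 8.59 ± 0.25 (9.24 on thinned libraries). The secretion gene gspE (1096627 to 1098279) rose by 9.30 ± 0.31, from 1.61 ± 0.216 to 1046 ± 188 CPM. Only 2 reads of gspG were counted in culture, and its ratio had a counting interval of 377 to 11247. The dicarboxylate transporter gene dctA1, the dctA copy with the highest mean CPM, rose by 6.10 ± 0.28. The list of 9 dicarboxylate transport genes, which does not hold dctA1, was not called (camera adjusted p 0.555). In it 0 genes rose and 4 fell (0 and 2 adjusted over the list alone), with a median of -0.21 and a highest change of 0.40.

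Of the 20 uptake hydrogenase genes, 15 rose and none fell (the same numbers adjusted over the list alone), with a median of 3.31 (camera adjusted p 5.30e-08; 0.652 with an estimated correlation). The subunit genes hupS and hupL rose by 5.02 ± 0.27 and 4.98 ± 0.30. In culture replicate 1 the median of this list differed from the other culture libraries by -0.57 on the log2 scale, and without that replicate 15 genes rose, 2 fell and the list's median change was 3.08 (adjusted p 1.31e-06). Calvin cycle genes were mixed, with 8 higher and 4 lower in A. afraspera nodules (8 and 4 adjusted over the list alone) and a median of 3.52 (camera adjusted p 0.0244; 0.927 with an estimated correlation). The Rubisco gene cbbL rose by 4.13 ± 0.41 and its neighbour cbbY by 4.07 ± 0.20, while cbbZ, chosen after its values were seen, fell by 0.95 (adjusted p 7.41e-05). This list was lower in culture replicate 1 (median -1.23), and without it 8 genes were higher and 4 lower, with a median change of 3.16 (adjusted p 0.00184).

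**Figure D1:**
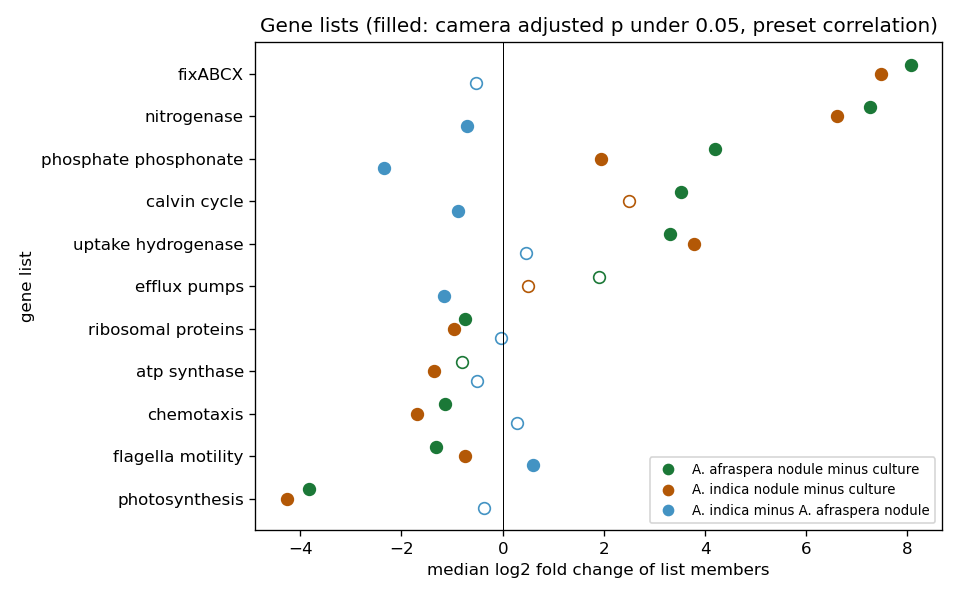
Median log2 fold change of the gene lists called in at least 1 comparison, with 1 point per comparison on an axis of log2 fold change. Filled points are list calls at the preset correlation, and the nitrogenase list lies at 7.27 and 6.61 against culture and at -0.71 between the nodule types.

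The 8 lowest changes under the naming rule were all of genes for bacteriochlorophyll synthesis. Of 30 photosynthesis genes 26 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -3.82 (camera adjusted p 6.74e-18; 0.175 with an estimated correlation). The bacteriochlorophyll synthesis gene bchF (5775351 to 5775983) stood at 3.41 ± 1.72 CPM in A. afraspera nodules and 175 ± 62.4 CPM in culture, a change of -5.97 ± 0.43 (adjusted p 5.40e-07; -5.38 without A. afraspera replicate 2). The changes of bchL and bchC were -5.94 ± 0.31 and -5.84 ± 0.35. The gene bchE fell by 5.59 (adjusted p 0.000286), and its culture level varied from 251 CPM in replicate 1 to 2050 CPM in replicate 2. Among reaction centre genes, puhA fell by 5.15, pufL by 4.88 and pufM by 3.55.

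Flagellar genes fell, 16 of 18 over all genes and 16 adjusted over the list alone, with a median of -1.31 (camera adjusted p 1.50e-05; 0.559 with an estimated correlation). The changes of flgG and flgH were -2.89 ± 0.20 and -2.43 ± 0.16. Of 15 chemotaxis genes 10 fell (11 adjusted over the list alone), with a median of -1.14 (camera adjusted p 0.000636; 0.652 with an estimated correlation). The changes of cheR_1 and cheA_1 were -3.32 ± 0.27 and -2.92 ± 0.25, and 38.9% of the reads of cheA_1 were not unique and left out. Ribosomal protein genes fell in 34 of 46 cases, and 1 rose (34 and 1 adjusted over the list alone). Their median was -0.75 (camera adjusted p 0.000403; 0.931 with an estimated correlation), and rpsI and rplB changed by -1.99 ± 0.16 and -1.33 ± 0.15.

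Among genes followed whatever their test, the cell-cycle regulator gene ctrA fell by 2.19, from 2875 ± 235 to 632 ± 112 CPM, and the division gene ftsZ by 0.83. The glutamine synthetase gene glnA rose by 0.78 ± 0.19 and the sigma factor gene rpoN by 0.58 ± 0.14. The nodulation gene nodC fell by 1.22 (adjusted p 0.0348), but its adjusted p ran from 0.00191 to 0.128 over 16 alternatives, the highest without A. afraspera replicate 3. The chaperonin gene groEL rose by 0.63 (adjusted p 0.0345; 0.00574 to 0.170 over the alternatives, the highest without A. afraspera replicate 2). Its call was also lost with the block for replicate number and without culture replicate 1 or 2, A. afraspera replicate 1 or A. indica replicate 2. The Nod factor gene nodA was not called in A. afraspera (change 1.20, adjusted p 0.0925; 0.00963 to 0.247 over the alternatives). No change was called for nodD1, ttsI, groL_1, recA, lexA, katG, rpoH and shc. Of these, nodD1 was called without A. afraspera replicate 3 (adjusted p 0.0122; 0.0122 to 0.415 over 16 alternatives), as was rpoH (0.0424; 0.0410 to 0.215, the lowest with DESeq2). The gene models BRAD285_v2_5666 and BRAD285_v2_5667, which have no symbol, rose by 9.88 and 9.49, while BRAD285_v2_3150 and BRAD285_v2_3151 fell by 7.98 and 7.91.

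The second comparison asks the same of nodules of A. indica. Most genes listed for nitrogenase, hydrogen uptake and phosphate uptake rose in A. indica nodules, and most listed for photosynthesis, chemotaxis, flagella, ribosomes and the ATP synthase fell. All these list calls were lost with an estimated correlation (adjusted p 0.108, 0.436, 0.373, 0.148, 0.727, 0.737, 0.879 and 0.868, in that order). Of 6657 genes, 3732 (56.1%) were called, 1964 higher and 1768 lower than in culture, and 2341 of them changed at least 2-fold (1414 higher, 927 lower). With no filter on low counts 1874 were higher and 1880 lower. The libraries of the groups did not overlap for 4431 genes (66.6%, where chance gives 10%).

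The nitrogenase list rose in 12 of 13 genes (12 adjusted over the list alone), with a median of 6.61 (camera adjusted p 1.01e-26; 0.108 with an estimated correlation). Without culture replicate 1 this median was 7.19. Transcripts of nifH_2 stood at 703 ± 129 CPM in A. indica nodules, a change of 10.15 ± 0.35 against culture (adjusted p 9.34e-09; 11.10 without culture replicate 3 and 9.44 on total reads), and nifH_1 changed by 10.04 ± 0.45 (10.87 without culture replicate 2). The changes of nifB, nifD and nifK were 8.44 ± 0.38, 7.33 ± 0.31 and 7.12 ± 0.33, and nifA rose by 5.71 ± 0.22. The iron-sulfur assembly gene iscA (1733655 to 1733978) rose by 7.88 ± 0.39 (8.61 without culture replicate 2 and 8.72 on thinned libraries). Against a floor of 3 counts fdxN_2 was 275-fold higher than in culture, where it had 0 counts. The 3 fix genes rose (3 adjusted over the list alone) with a median of 7.48 (camera adjusted p 3.72e-10; 0.108 with an estimated correlation), led by fixA at 7.79 ± 0.30.

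Of the 20 uptake hydrogenase genes 15 rose and none fell (15 adjusted over the list alone), with a median of 3.79 (camera adjusted p 1.01e-11; 0.436 with an estimated correlation), and without culture replicate 1 the numbers were 16 higher and 1 lower, with a median of 3.57 (adjusted p 2.39e-10). The changes of hupC and hupS were 5.81 ± 0.30 and 5.62 ± 0.28. The dicarboxylate transporter gene dctA1 rose by 7.04 ± 0.29, from 5.09 ± 1.38 to 669 ± 21.8 CPM. The list of 9 dicarboxylate transport genes, which does not hold dctA1, was not called (camera adjusted p 0.742). In it 1 gene rose and 2 fell (1 and 2 adjusted over the list alone), with a median of -0.15. In the phosphate list 7 of 9 genes rose (7 adjusted over the list alone), with a median of 1.95 (camera adjusted p 0.000369; 0.373 with an estimated correlation). Here pstS rose by 2.15 ± 0.18, phoB by 2.70 ± 0.27 and phnC by 5.21 ± 0.24. The Calvin cycle list was not called against culture in A. indica (camera adjusted p 0.281), with 7 genes higher and 5 lower (7 and 5 adjusted over the list alone) and a median of 2.50. Without culture replicate 1 the numbers were also 7 and 5, with a median of 2.14 (adjusted p 0.136).

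Photosynthesis genes fell in 26 of 30 cases and 1 rose (26 and 1 adjusted over the list alone), with a median of -4.27 (camera adjusted p 6.81e-23; 0.148 with an estimated correlation). The bacteriochlorophyll genes bchN, bchL and bchF changed by -6.56 ± 0.38, -6.44 ± 0.33 and -6.25 ± 0.46, and pufL by -5.37 ± 0.35. Of 15 chemotaxis genes 13 fell (13 adjusted over the list alone), with a median of -1.69 (camera adjusted p 0.000375; 0.727 with an estimated correlation), cheR_1 by 2.95. Flagellar genes fell in 12 of 18 cases and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.75 (camera adjusted p 0.00266; 0.737 with an estimated correlation). Here flgG changed by -2.22 ± 0.19.

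Ribosomal protein genes fell in 33 of 46 cases (36 adjusted over the list alone), with a median of -0.96 (camera adjusted p 2.75e-05; 0.879 with an estimated correlation), rpsG by 1.77 and rpmE by 1.47. The ATP synthase list fell in 8 of 9 genes (8 adjusted over the list alone), with a median of -1.36 (camera adjusted p 0.00352; 0.868 with an estimated correlation), and atpH and atpG changed by -1.67 ± 0.16 and -1.55 ± 0.17. In A. afraspera the same list had a median of -0.81 and was not called (camera adjusted p 0.105), and between the nodule types it was not called either (adjusted p 0.309).

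Of the genes followed whatever their test, ctrA fell by 1.55, glnA by 0.77 and the catalase-peroxidase gene katG by 1.66. The gene nodA stood at 351 ± 269 CPM in A. indica nodules and rose by 2.12 ± 0.57 (adjusted p 0.0123; 3.49e-05 to 0.0452 over 16 alternatives), or by 1.32 without A. indica replicate 3. The repressor gene lexA rose by 0.57 (adjusted p 0.0210; 0.0141 to 0.145 over 16 alternatives, the highest without A. indica replicate 2). No change was called for nodC, nodD1, ttsI, groEL, groL_1, ftsZ, recA, rpoN, rpoH and shc. Of these, groL_1 was called lower without A. indica replicate 3 (adjusted p 0.00792; 0.00792 to 0.269 over 16 alternatives) and without A. afraspera replicate 3 (0.0401). The gene ftsZ was called lower in the fit on 6 libraries (0.0196; 0.0196 to 0.231) and without A. afraspera replicate 3 (0.0428), and shc in the fit on 6 libraries (0.0403; 0.0357 to 0.251) and without A. indica replicate 2 (0.0357). Among models without a symbol, BRAD285_v2_1806 and BRAD285_v2_1784 rose by 8.16 (7.26 on thinned libraries) and 8.01, and BRAD285_v2_3151 and BRAD285_v2_3200 fell by 7.06 and 6.62.

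Genes called in both nodule types mostly went the same way. Of 6657 genes, 1481 rose and 1390 fell in both, 2871 in all. Independent lists of these sizes would share 1125. Another 75 genes went opposite ways, and all 75 were also called between the nodule types. That call follows almost by construction, since the change between the nodule types is the difference of the 2 changes against culture. Both comparisons use the same 3 culture libraries, which alone correlates their changes: the correlation across genes was 0.877, against a mean of 0.504 over 50 simulations of unchanged groups. The covariance of the changes was 2.36 against 0.0434 in the simulations, in which at most 1 gene was called in the same direction in both. The simulations hold no changed genes, and the covariance that shared culture error gave in them was thus small beside the observed one. For the count of genes, the part of the excess over 1125 that comes from the shared libraries was not separated. The reason is that 3 culture libraries cannot be split into separate control sets of 2.

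**Figure D2:**
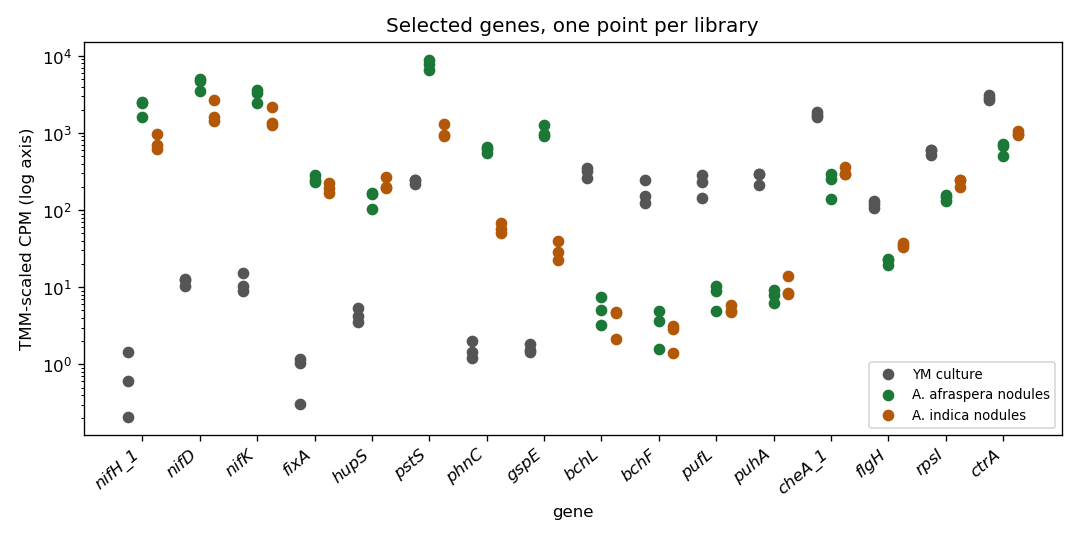
Normalised read counts (CPM, logarithmic axis) of selected genes, with 1 point per library, coloured by group. Levels of nifD average 4451 in A. afraspera nodules and 11.9 in culture, and levels of pstS average 7732 and 239.

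The third comparison asks how the mutant's transcripts differ between nodules of A. indica and of A. afraspera. All tested genes listed for phosphate uptake and efflux pumps were lower in A. indica nodules, as were most nitrogenase and Calvin cycle genes, while 9 of 18 flagellar genes were higher. With an estimated correlation the phosphate call alone was kept (adjusted p 0.0204), against 0.412 for efflux pumps and 0.918 for each of the other 3 lists, and the flagella call was also lost without A. afraspera replicate 3 (adjusted p 0.112) and the Calvin cycle call without A. afraspera replicate 1 (0.0718). Lower as well was a stretch of 23 gene models around gspE, and higher were vanA, for the breakdown of aromatic compounds, and the molybdate-binding protein gene modA. Of 6657 genes, 2033 (30.5%) were called, 1124 higher and 909 lower in A. indica, and 882 of them changed at least 2-fold (504 higher, 378 lower). The fit on the 6 libraries compared called 848 higher and 858 lower, and without A. indica replicate 1 the numbers were 765 and 604. The libraries of the groups did not overlap for 2771 genes (41.6%, where chance gives 10%).

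All 9 phosphate genes were lower in A. indica nodules (9 also adjusted over the list alone), with a median of -2.34 (camera adjusted p 8.87e-22). This list call was kept with an estimated correlation (adjusted p 0.0204). Transcripts of pstS stood at 1057 ± 205 CPM in A. indica nodules and 7732 ± 1116 CPM in A. afraspera nodules, a change of -2.87 ± 0.19 (adjusted p 6.24e-07). The changes of pstC, phoB, phoR and phnC were -2.35 ± 0.18, -2.66 ± 0.25, -1.85 ± 0.14 and -3.39 ± 0.18. The phospholipase C gene plcN_1 (5732602 to 5734731) had the lowest change under the naming rule, at -7.09 ± 0.30, from 5528 ± 631 CPM in A. afraspera to 41.2 ± 16.3 CPM in A. indica.

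The secretion genes gspE, gspG and gspF changed by -5.11 ± 0.24, -5.02 ± 0.29 and -4.49 ± 0.32. They are the 3 models with a symbol in a stretch of 23 neighbouring gene models (1090072 to 1114498), chosen after its values were seen. The median change of the stretch was -4.56. All 23 were at least 4-fold lower in A. indica, since the stretch was drawn by that rule. The transporter gene gsiC_2 changed by -4.36 ± 0.21 and dapA_1 by -3.28 ± 0.20. Of the 7 efflux pump genes all 7 were lower in A. indica nodules (7 adjusted over the list alone), with a median of -1.15 (camera adjusted p 1.91e-05; 0.412 with an estimated correlation), and mdtA_1 and mexB changed by -1.26 ± 0.16 and -1.15 ± 0.16. Against culture, the efflux genes went both ways in each nodule type, with 5 higher and 2 lower in A. afraspera and 4 higher and 2 lower in A. indica, where the median was 0.51 but the mean -0.51 and the test's direction lower (camera adjusted p 0.580).

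**Figure D3:**
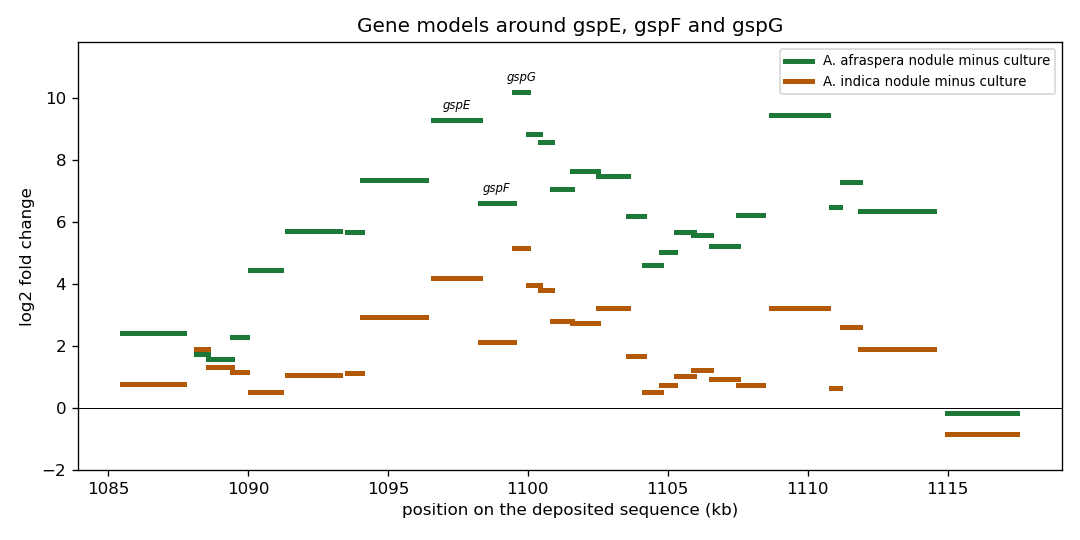
Log2 fold change against culture (vertical axis) of each tested gene model, drawn as a bar from its start to its end (position in kb), in A. afraspera (green) and A. indica nodules (brown). In A. afraspera gspE lies at 9.30. The bars of the 23 gene models from 1090072 to 1114498 all lie higher in A. afraspera than in A. indica nodules, since the stretch was drawn by that difference.

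Of the 13 nitrogenase genes 9 were lower and 1 higher in A. indica nodules (11 and 1 adjusted over the list alone), with a median of -0.71 (camera adjusted p 0.00621; 0.918 with an estimated correlation). The changes of nifH_1, nifD and nifX were -1.53 ± 0.27, -1.21 ± 0.24 and -0.96 ± 0.18, and nifD stood at 1919 ± 682 CPM in A. indica. The gene nifK fell by 0.97 (adjusted p 0.0129; 0.00283 to 0.0599 over 16 alternatives, the highest without A. indica replicate 1). In contrast, nifA was higher in A. indica by 0.70 ± 0.18. Calvin cycle genes were lower in 8 of 13 cases (10 adjusted over the list alone), with a median of -0.89 (camera adjusted p 0.0175; 0.918 with an estimated correlation), and this list call was lost without A. afraspera replicate 1 (adjusted p 0.0718; 0.00110 to 0.0718 over 13 alternatives other than the list tests). Here cbbY changed by -0.89 ± 0.17.

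Flagellar genes were higher in A. indica nodules in 9 of 18 cases (10 adjusted over the list alone), with a median of 0.61 (camera adjusted p 0.0240; 0.918 with an estimated correlation), and this list call was lost without A. afraspera replicate 3 (adjusted p 0.112; 0.00825 to 0.112 over 13 alternatives). The genes flgB, flhB and fliI were higher by 1.45 ± 0.17, 1.34 ± 0.17 and 1.14 ± 0.15. Among single genes, nhr3 (5411509 to 5412714) was highest under the naming rule at 4.36 ± 0.43, followed by the aldehyde dehydrogenase gene aldB at 4.29 ± 0.61. The gene modA was higher by 2.94 ± 0.27, at 152 ± 19.9 CPM in A. indica and 18.9 ± 7.94 CPM in A. afraspera. The gene vanA was higher by 2.72 ± 0.18. The gene boxB was higher by 2.45 ± 0.49, at 803 ± 584 CPM in A. indica, and by 1.67 without A. indica replicate 3.

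Of the genes followed whatever their test, glnA changed by -1.55 ± 0.19 and katG by -1.96 ± 0.28, while dctA1 and ctrA were higher in A. indica by 0.94 ± 0.21 and 0.63 ± 0.16. The gene hupS was higher by 0.60 (adjusted p 0.0474; 0.0349 to 0.146 over 16 alternatives, the highest without A. indica replicate 3). Its call was lost in most alternatives. These were no filter on low counts, the fit on 6 libraries, thinned libraries and the fits without A. afraspera replicate 1 or 3. The call was also lost whichever culture or A. indica library was left out. The sigma factor gene rpoN fell by 0.53 (adjusted p 0.0148; 0.00180 to 0.0612 over 16 alternatives, the highest without A. indica replicate 1). The hopanoid synthesis gene shc fell by 0.59 (adjusted p 0.0245; 0.0108 to 0.0992 over 16 alternatives, the highest without A. indica replicate 1). No difference was called for fixA, nodA, nodC, nodD1, ttsI, groEL, groL_1, hupL, pufL, pufM, ftsZ, recA, lexA and rpoH. Of these, nodC was called higher with DESeq2 (adjusted p 0.0211; 0.0140 to 0.238 over 16 alternatives) and without A. indica replicate 2 (0.0140), culture replicate 1 (0.0455) or A. afraspera replicate 1 (0.0486). Without A. afraspera replicate 2 hupL (0.0328; 0.0328 to 0.256) and ftsZ (0.0151; 0.0151 to 0.167) were called higher. The gene nodD1 was called lower without A. afraspera replicate 3 (0.0306; 0.0306 to 0.553) and groL_1 without A. indica replicate 3 (0.0363; 0.0363 to 0.609). Among models without a symbol, BRAD285_v2_6154 and BRAD285_v2_7023 were higher by 5.26 (4.63 without A. afraspera replicate 2) and 4.03, and BRAD285_v2_1078 and BRAD285_v2_4125 fell by 6.22 and 5.89.

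**Figure D4:**
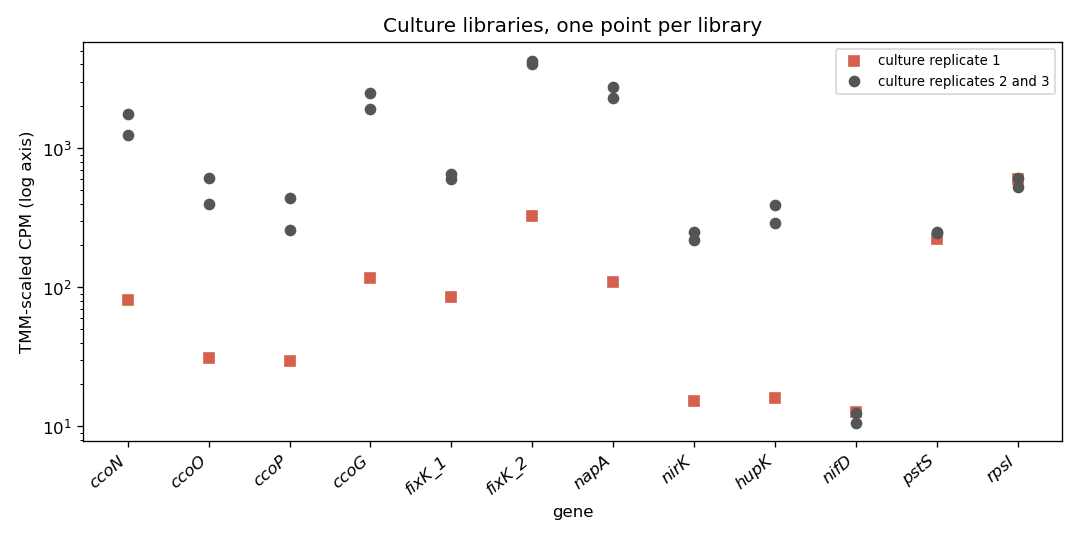
Normalised read counts (CPM, logarithmic axis) in the 3 culture libraries of 9 genes lower in replicate 1 (squares) than in replicates 2 and 3 (circles), chosen after their values were seen, and of nifD, pstS and rpsI beside them. The cbb3 oxidase gene ccoN stood at 80.5 CPM in replicate 1 and at 1766 and 1252 CPM in the others.

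The cbb3 oxidase and denitrification lists were called in no comparison. In the cbb3 list 4 genes rose and 1 fell in A. afraspera nodules, and 2 rose and 1 fell in A. indica nodules (the same numbers adjusted over the list alone). Culture replicate 1 lay below the others in this list (median -3.57) and in the denitrification list (median -1.04). In the denitrification list 7 genes rose and 2 fell in A. afraspera nodules (7 and 3 adjusted over the list alone), and 2 rose and 2 fell in A. indica nodules (1 and 1 adjusted over the list alone). Without culture replicate 1, 5 cbb3 genes rose and 3 fell in A. afraspera nodules, with a median of 0.42 (0.87 with it), and 4 rose and 2 fell in A. indica nodules, with a median of 0.21 (0.58 with it). The cbb3 list was then not called either (adjusted p 0.865 and 0.971). Without this replicate 6 denitrification genes rose and 4 fell in A. afraspera nodules, with a median of 0.74 (0.90 with it) and no call (adjusted p 0.528). In A. indica nodules 2 rose and 6 fell and the denitrification list was called lower (median -0.55, adjusted p 0.0336), and with the replicate the adjusted p was 0.756 and the median -0.36.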

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

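The tests of scaling between the nodule types and of the models that hold non-unique reads were chosen after the results were seen. The nodule types are singled out here because the difference between them was itself tested, as A. indica minus A. afraspera in the edgeR model. It was called for 2033 genes, and 75 of these moved in opposite directions against culture. The gene lists concerned were phosphate (median -2.34), efflux pumps (-1.15), Calvin cycle (-0.89), nitrogenase (-0.71) and flagella (0.61), of which the first alone was called with an estimated correlation (adjusted p 0.0204). The Calvin cycle call was lost without A. afraspera replicate 1 (adjusted p 0.0718; 0.00110 to 0.0718 over 13 alternatives) and the flagella call without A. afraspera replicate 3 (0.112; 0.00825 to 0.112). Against culture glnA rose in A. afraspera by 0.78 and fell in A. indica by 0.77, and its difference between the nodule types was -1.55. The difference was 2.72 for vanA and 2.94 for modA.

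For the phosphate list the tables argue against 3 technical explanations. If a lone library decided the pattern, fewer genes would be called without it, but 9 of 9 genes were called lower in each of the 6 fits that left out a nodule library. After all 9 libraries were thinned to the smallest total, which removes the greater depth of A. afraspera replicate 2, 9 of 9 genes were called. Under TMM, RLE, upper-quartile and plain total scaling the list's median was at most -2.22, while plain totals moved the median of all genes from 0.0413 to 0.168. The host plant stays open as an explanation, and a lower phosphate supply to the bacteria in A. afraspera nodules, which was not tested, is a candidate explanation of that kind.

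The 3 groups were also compared with other splits of the same libraries. For A. afraspera nodules and culture, 1 of the 10 splits of 6 libraries, the real one, gave 4006 genes in edgeR, and the highest other gave 0 (155 at an unadjusted p under 0.05, against 4271). For A. indica nodules and culture 1 of 10 splits gave 3732 genes, and the highest other 0 (242 against 4050 unadjusted). Between the nodule types 1 of 10 splits gave 2033 genes, and the highest other 0 (840 against 2825 unadjusted). With 10 splits no share under 0.05 can be reached. Each other split mixes libraries of both groups, so the difference between the groups widens its spread and few genes can be called. Nothing is concluded from these numbers.

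Signal outside the unique counts was found in reads that the total column holds in addition. In 115 gene models there were total reads but no unique read in any library. In the nodule libraries 23696 such reads fell on nifH_1 and 13437 on nifH_2, against 6 and 9 in culture. Non-unique reads made up 1.92% ± 0.0929 of the total in culture, 0.945% ± 0.0619 in A. afraspera and 0.921% ± 0.0694 in A. indica nodules (SD, n = 3). A candidate explanation for the larger share in culture is that a few abundant gene models have near-identical copies. In the culture libraries 5 gene models held at least 60.96% of the non-unique reads, against at most 33.7% in the nodule libraries. These models were selected for their reads, and no biological explanation was tested.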

How the results depend on the processing

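The alternatives with total reads and with thinned libraries were chosen after seeing the data. The counts of called genes stayed within 1.5 times their value under RLE scaling, no filter, DESeq2, a block for replicate number and both added alternatives, as did those of the fits on 6 libraries (4010, 3836 and 1706 genes for A. afraspera minus culture, A. indica minus culture and A. indica minus A. afraspera). DESeq2 called 4019, 3785 and 2182 genes. With a log2 fold change of at least 1 required, which by construction removes genes, the counts were 2576, 2341 and 882, and 1788 genes changed the same way in both nodule types. Leaving out each library in turn gave 3521 to 4094, 3245 to 3820 and 1369 to 2022 called genes, and 2487 to 2852 genes shared in direction.

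With an estimated correlation camera called 0, 0 and 1 lists in place of 9, 9 and 5 (4, 4 and 2 lists at an unadjusted p under 0.05). The estimated correlations of the called lists exceed the preset one, which widens the test by construction. The other tool, fry, which compares a list with no other genes, called 21, 24 and 11 lists, and the cause of the larger numbers was not tested. Leaving out each library in turn gave 9 to 11, 9 to 10 and 4 to 9 lists, and the 9 lists between the nodule types were called without A. afraspera replicate 2; the cause was not tested. No called list and no called change of a named gene turned direction under any alternative, while uncalled changes did, as for nodC in A. indica minus culture (-0.73 to 0.21). In the fits that left out a library, results for single named genes lost a call 31 times, gained one 16 times and stayed on their side 1798 times, and DESeq2 and the fits on 6 libraries gained 3 each. The fits on 6 libraries, with no filter, with the block and on thinned libraries lost 1 each. On raw totals 20 of the CPM means of genes selected by the naming rule, printed or not, moved by more than their SD and 316 did not. The alternative without ribosomal and transfer RNA was not run, since the tables name no such feature. Depth limits what can be seen near 3 counts, between 0.162 and 1.59 CPM.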

Other observations

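The tests in culture replicate 1 of scaling, of RNA from nodule bacteria and of denitrification genes were chosen after the result was seen. Culture replicate 1 had 183 of 5338 genes more than 2-fold below the mean of the other culture libraries and 66 more than 8-fold below, with 1 CPM added. Its level of ccoN was 80.5 CPM, against 1766 and 1252 CPM in replicates 2 and 3, that of napA 109 against 2768 and 2281 CPM, and that of fixK_2 327 against 4264 and 4052 CPM (genes chosen after their values were seen). The cbb3 oxidase list had a median log2 difference of -3.57.

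The tables argue against 3 technical explanations of this pattern. After thinning to the smallest culture total, which removes the difference in depth, the cbb3 median was still -3.57, and under TMM, RLE, upper-quartile and plain total scaling it was at most -3.49, with medians over all tested genes of -0.00693 to 0.0696. RNA of nodule bacteria in replicates 2 and 3 would raise nifD and nifK there, but their mean difference was 0.382, with replicate 1 the higher. A lower oxygen supply in culture replicates 2 and 3 is a candidate explanation, although the labels give no such difference: the denitrification list lay at the 0.01 percentile of 10000 random lists matched on expression, the smallest they can give, and its 9 members other than 4 genes already looked at had a median of -0.68, at the 0.08 percentile. Some of these 9 members carry the nap and nos stems of genes already looked at, so they are not a separate test. The random lists were matched on expression and not on shared regulation. The Calvin cycle and hydrogenase lists also lay at the 0.01 percentile, and nodulation, photosynthesis and type III secretion at 100, 99.9 and 99.7, so that the percentile does not single out the oxygen explanation.

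Some changed genes lay in blocks along the sequence, all chosen after their values were seen. Runs of at least 5 neighbouring models held 220 of the 649 genes at least 4-fold higher in A. afraspera nodules and 81 of the 383 lower. In A. indica nodules they held 217 of 680 higher and 69 of 287 lower genes, so most lay outside such runs. In A. afraspera nodules a run of 70 neighbouring gene models from 1706108 to 1758076, from before nifA to past fixC, was at least 4-fold higher than in culture, with a median of 6.81. In A. indica nodules the run held 75 models up to 1763406 (median 5.93). The longest run in 1000 shuffles of gene order held 7 models. Among lower genes, 19 models from bchJ to bchG (5757756 to 5779511) had medians of -5.10 and -5.18 in A. afraspera and A. indica nodules, and 12 models from pufM to crtD (5787907 to 5799773) had medians of -3.78 and -4.74. The longest shuffled run of lower genes held 4 models. Shuffling separates neighbouring genes that may share a transcript, so runs longer than the shuffled ones cannot tell more than that, and nothing further is concluded.

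Some cell-cycle genes were looked at after their values were seen. The replication initiator gene dnaA fell by 1.89 in A. afraspera and by 1.08 in A. indica nodules, and the difference between the nodule types was 0.81 (adjusted p 0.00392). The septum-placement genes minC, minD and minE were higher in A. indica than in A. afraspera nodules by 1.26, 0.92 and 0.89 (adjusted p 0.00161, 0.0132 and 0.0159). The list of 21 cell-cycle genes was called in no comparison (camera adjusted p 0.0629, 0.235 and 0.345), with 11 genes lower in A. afraspera nodules (11 adjusted over the list alone), 3 higher and 9 lower in A. indica nodules (3 and 10) and 6 higher and 1 lower between the nodule types (9 and 1, median 0.31), although it was called in A. afraspera without culture replicate 1 (adjusted p 0.0458).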
